A study of Homo sapiens with 8 samples.

How the data were processed

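Polyadenylated RNA from 8 cultures of SaOS-2 cells was sequenced by the study, 4 on flat and 4 on micropillared PDMS, with 1 culture per surface from each of passages 8, 9, 11 and 13. Per the labels' protocols, RNA was taken up in TRIzol and purified on columns, and libraries followed standard Illumina procedures. Per the submitters' processing notes, bcl2fastq, cutadapt, STAR 2.7, RSEM 1.3, edgeR 3.34.1 and R 4.1.1 were used with the human build GRCh38.p13. Their parameters, the strandedness of the libraries and the filter that set which genes were listed are not given in the sources used here. The deposited values are a normalized signal, named CPM by the authors: CPM computed on a library size that had been scaled, since the 8 columns summed to 976342 to 1038186, 4 of them above the total that plain CPM would give. Each deposited value was close to a multiple of 0.01 read, as fits RSEM's estimated counts. Of the values per library, 72.9% to 74.1% were whole reads within a tolerance of 0.001 read. Because that share was too low for whole reads to be recovered, the count model of edgeR was not used, and the values were treated as a signal on a log scale although CPM had been planned for. The number of columns that could not be tied to a sample was 0.

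The deposited table listed 13477 genes, with a lowest mean of 0.349 CPM, so genes below that level are not analysed here. Estimated reads over the listed genes were 36200000, 36800000, 33700000 and 38900000 for the flat libraries of passages 8, 9, 11 and 13, and 29300000, 40500000, 33000000 and 34200000 for the pillar libraries. The 10 most abundant genes took 4.9% to 5.87% of each library. At this depth 1 read was worth 0.0245 to 0.0341 CPM, so counting error was small for abundant genes. At a few CPM it was not negligible: standard errors of the log2 fold change were 0.08 for PTH1R and 0.10 for HES4, against 0.05 for the abundant HDAC2. Gene identifiers of 13445 listed genes matched GENCODE release 29, from which coordinates on GRCh38, GC content and transcript length were taken, the latter 2 for 99.7% of the genes.

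Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with surface and passage as terms, a mean-variance trend and two-sided p-values. The 12670 genes with a mean of at least 1 CPM over all 8 libraries entered the fit, the other 807 did not, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. Passage entered as a fixed block because the series describes a paired design by passage. As a check, deviations from the group means were correlated across genes, which are not independent replicates. Libraries of 1 passage gave r = 0.33, 0.54, 0.64 and 0.43 for passages 8, 9, 11 and 13, and libraries of different passages gave -0.50 to 0.32. Deviations from a mean cancel within each surface, so negative values between passages are partly built in, and the value of passage 8 hardly exceeded the highest of them. Without the block, 591 genes passed in place of 1826.

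The 45 gene lists were fixed before the data were examined, as were the test, the design, the threshold, the alternatives not said to be added later, and the rule for naming genes. Lists with at least 5 measured members (41 of them) were tested with limma camera at a preset correlation of 0.01 between genes, which compares a list with all other genes. With the correlation estimated from the data no list passed, 4 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.20. The test fry, which tests whether the genes of a list move 1 way on balance, called 23 lists, 19 of them shared with the 22 called by camera. Some members were matched by Ensembl identifier only (15 of them, among them the mitochondrial genes). Named genes were the 10 largest rises and the 10 largest falls that passed the threshold with the same direction in 4 of 4 pairs. To these came a fixed set around histone deacetylases, the lamina, YAP targets and bone, and up to 4 members of lowest p from each called list and from 6 lists kept in any case, which gave 122 genes. Members behind small counts that this rule did not name, such as LATS2, RCOR2 or PIEZO1, were named after their values were seen and were not refitted under the alternatives. A few of the genes and 1 gene list are not reported here.

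The procedure was tested on simulated data for the pillar against flat comparison, with values drawn for 12625 genes and 200 of them changed. It recovered 76% of the genes changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, and 13 of 200 calls were false. With no change simulated it made 0 calls, a shifted list was called, and 0 of 39 other lists were. The simulated noise was independent between genes and the lists were random genes, so false calls of lists whose members vary together were not tested. In the measured data the estimated correlation within a list was, for example, 0.59 for SRF and MRTF targets and 0.92 for cytosolic ribosomal proteins. Alternatives covered the block (absent, or passage as a random block), the pseudocount (0.1 and 4), the filter on low values (none, and a mean of 5 CPM), the scaling (median ratios, equal totals and quantiles), the variance model (no trend, robust) and each passage pair left out. After the data were seen, 3 more were added: limma-voom on estimated reads, removal of GC and length trends, and thinning to the shallowest library. So were camera with a variance trend, and cameraPR on the moderated t for lists under a random block or a robust variance, which camera does not take. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 in R, were used besides limma, with a random seed of 1 where values were drawn.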

Results

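Gene expression was measured by RNA sequencing of polyadenylated RNA in SaOS-2, an established human osteosarcoma line with osteoblast-like properties. The cells were grown on PDMS, a silicone elastomer, whose surface was either flat or covered with micropillars. By its title, the series used micropillars in a screen on how readily nuclei deform, with the histone deacetylase HDAC2 as its subject, and the RNA libraries ask which transcripts differ between the surfaces. There were 2 groups of 4 libraries, taken 48 h after seeding on surfaces coated with a basement membrane extract at 50 µg/ml. Passages 8, 9, 11 and 13 of the line each gave 1 flat and 1 pillar library, and these separate passages were the replicates. The libraries held between 29300000 (pillar, passage 8) and 40500000 (pillar, passage 9) estimated reads over 13477 listed genes, so that 1 read was worth 0.0245 to 0.0341 CPM.

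On micropillars, genes of bone-forming cells rose, while the cytokine IL11, the carboxypeptidase CPA4 and genes of the contractile cytoskeleton fell. Of 17 osteoblast markers 13 rose, and of 36 actomyosin genes 16 fell and 1 rose (limma camera, Benjamini-Hochberg adjusted p = 1.31e-10 and 8.48e-08; adjusted p = 0.20 and 0.319 with an estimated correlation). IL11 (chromosome 19, 55364389 to 55370463, GRCh38) fell from 219 ± 38.2 CPM on flat to 66.7 ± 10.1 CPM on pillars (SD, n = 4), 3.24-fold lower on the log2(CPM + 1) scale. TMEM119 (chromosome 12, 108589846 to 108598320) encodes a membrane protein that promotes osteoblast differentiation. On the same scale it had the largest rise among passing genes higher in 4 of 4 pairs, from 35.8 ± 14.3 to 136 ± 60.4 CPM, 3.66-fold. Of 12670 genes tested with limma and Benjamini-Hochberg adjustment, 1826 passed an adjusted p of 0.05, of which 895 rose and 931 fell. A change of at least 1.5-fold was found for 317 of them, 156 higher and 161 lower. Without the passages as a block 591 genes passed, 195 with at least 1.5-fold, and without the passage 13 pair 1022 genes passed.

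The 10 largest rises among genes higher in 4 of 4 pairs ran from a log2 fold change of 1.87 (TMEM119) to 1.39 (PANX3). They included EPYC (1.78) and PRELP (1.44), small leucine-rich proteoglycans of skeletal matrix, PHOSPHO1 (1.42), a phosphatase of matrix vesicles that starts mineralization, and IFITM5 (1.42), a membrane protein of mineralizing osteoblasts. PANX3, a channel protein of osteoblasts and chondrocytes, went from 69.3 ± 19.6 to 182 ± 45.4 CPM. MELTF (1.67), INSC (8.14 ± 3.73 to 24.4 ± 9.02 CPM), ENTPD3 (1.46) and the long noncoding RNA LOC102724701 (1.64) completed the group. Among the 10 largest falls were CPA4 (-2.18, from 75.3 ± 11.5 to 16.2 ± 4.46 CPM), the noncoding RNA FLJ22447 (-2.27), IL11 (-1.70), the aldehyde oxidase AOX1 (-1.52), IGFN1 (-1.42) and RAB3B (-1.41). CGB5 (-2.13), CGB3 (-1.72) and CGB8 (-1.57), neighbouring copies of the gene for the beta chain of chorionic gonadotropin, fell as well. The values of these copies and of LOC102724701, which lies in a part of chromosome 21 with a near-identical copy, are uncertain because reads could be divided between copies. With limma and no block, EPYC, IFITM5 and IGFN1 did not pass (adjusted p = 0.0539, 0.173 and 0.107), and LOC102724701 did not pass with a robust variance (adjusted p = 0.146).

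**Figure D1:**
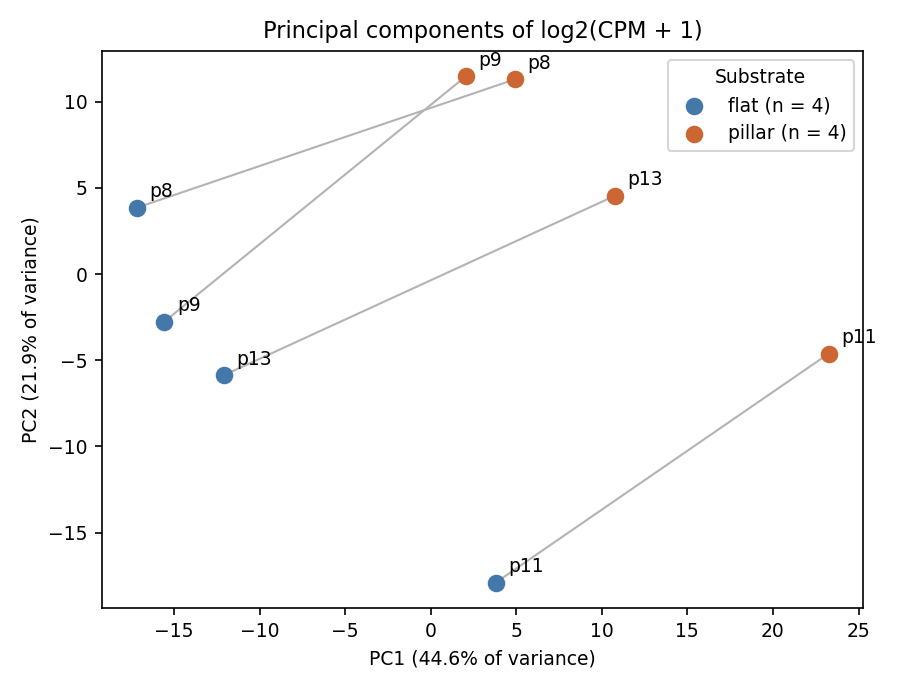
Each point is 1 library placed by its first and second principal components of log2(CPM + 1), coloured by surface, labelled by passage (p8 to p13), with grey lines joining the libraries of 1 passage. In each of the 4 passages the pillar library lies at a higher PC1 than its flat partner, by 17.64 to 22.82 units, and both passage 11 libraries lie to the right of the other libraries of their surface.

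The first principal component held 44.6% of the variance and the second 21.9%. Pillar libraries lay higher on the first component than the flat library of their passage, by 17.64 (passage 9) to 22.82 (passage 13). Both passage 11 libraries stood apart: the flat one was at 3.81, against -17.16 to -12.07 for the other flat libraries, and the pillar one was at 23.25, against 2.07 to 10.75. Leaving out the passage 11 pair gave 1782 genes, 1512 of them shared with the full set.

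Osteoblast markers rose on pillars: 13 of 17 measured members rose and none fell, 13 also when adjusted over the list alone, with a median log2 fold change of 0.40 (limma camera, Benjamini-Hochberg adjusted p = 1.31e-10; adjusted p = 0.20 with an estimated correlation). The list held 24 symbols, and the others, among them BGLAP, SPP1 and DMP1, were not among the listed genes. SP7 (chromosome 12, 53326575 to 53345315), the transcription factor osterix, rose from 57.2 ± 22.5 to 132 ± 39.6 CPM (log2 fold change 1.22, SE 0.06, limma adjusted p = 8.40e-09). The receptor for parathyroid hormone, PTH1R, rose by a log2 fold change of 1.24, from 3.83 ± 1.33 to 10.3 ± 2.62 CPM. ALPL (chromosome 1, 21509372 to 21578412), the tissue-nonspecific alkaline phosphatase, was abundant and rose from 1383 ± 150 to 2148 ± 42.6 CPM (0.64, SE 0.06, limma adjusted p = 9.49e-06). RUNX2, the transcription factor that commits cells to the osteoblast lineage, rose less, from 190 ± 5.56 to 220 ± 5.24 CPM (0.22, SE 0.05, limma adjusted p = 0.00729). RUNX2 did not pass without the passage 9 pair (adjusted p = 0.0570) or the passage 13 pair (adjusted p = 0.0559). Of 7 chondrocyte markers, which overlap in function with osteoblast matrix genes, 3 rose and none fell, against 4 and 1 when adjusted over the list alone (median 0.32, camera adjusted p = 0.0408; adjusted p = 0.319 with an estimated correlation). The higher ones were the matrix link protein HAPLN1 (0.88, 367 ± 43.0 to 682 ± 99.8 CPM), the transcription factor SOX6 (0.63) and COL10A1 (0.37). COL9A2 was lower in 4 of 4 pairs (-0.21, limma adjusted p = 0.0526) and passed in some other fits, such as quantile normalization (adjusted p = 0.0350). SOX9 did not pass (-0.08, limma adjusted p = 0.482). Only 8 of the 17 symbols in this list were among the listed genes. The chondrocyte list was not called without the block, with a random block, without the passage 8 pair, with a pseudocount of 0.1, with no filter, after scaling to equal totals or quantiles, or after removal of GC and length trends. Without the block SOX6 and COL10A1 did not pass (limma adjusted p = 0.413 and 0.596), and COL10A1 did not pass with any 1 pair left out either (adjusted p = 0.117, 0.0677, 0.137 and 0.0789 without passages 8, 9, 11 and 13).

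Genes of the contractile cytoskeleton fell. In the actomyosin list, 16 of 36 members fell and 1 rose, against 19 and 2 when adjusted over the list alone (median -0.16, limma camera, Benjamini-Hochberg adjusted p = 8.48e-08; adjusted p = 0.319 with an estimated correlation). Calponin CNN1 (chromosome 19, 11538717 to 11550323) fell from 165 ± 27.7 to 65.5 ± 5.37 CPM (log2 fold change -1.30, SE 0.06, limma adjusted p = 8.40e-09). The small GTPase RHOB (-0.75), the filamin FLNC (-0.54) and the actin-severing protein CFL2 (-0.42) fell in 4 of 4 pairs. The myosin light chain kinase MYLK was the member that rose (0.31). Targets of SRF and its MRTF coactivators, which respond to the actin monomer pool, fell in 11 of 21 cases and rose in 1, against 14 and 1 when adjusted over the list alone (median -0.21, camera adjusted p = 5.85e-09; adjusted p = 0.319 with an estimated correlation). This list shared 9 members with the actomyosin list. Its examples were TAGLN (-1.08, from 417 ± 114 to 193 ± 28.3 CPM) and FHL2 (-0.88), a LIM protein that binds actin filaments, against SYNPO2, which rose (0.67) but did not pass without the block (limma adjusted p = 0.149).

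Targets of the transcriptional coactivators YAP and TAZ fell in 12 of 26 cases and rose in 1, against 13 and 1 when adjusted over the list alone (median -0.14, limma camera, Benjamini-Hochberg adjusted p = 1.04e-06; adjusted p = 0.319 with an estimated correlation). The abundant matricellular gene CCN1 fell from 1638 ± 114 to 1271 ± 94.8 CPM (log2 fold change -0.37, limma adjusted p = 0.00136). CCN2 fell from 111 ± 37.1 to 68.3 ± 19.1 CPM (-0.68), ANKRD1 by a log2 fold change of -1.28 (SE 0.07) and the receptor tyrosine kinase AXL from 745 ± 72.0 to 467 ± 30.3 CPM (-0.67). TGFB2 fell as well (-0.47), while the kinase LATS2, which restrains YAP, was the member that rose (0.26). CCN2 and ANKRD1 fell in 4 of 4 pairs, but their levels varied between passages and neither passed without the block (limma adjusted p = 0.157 and 0.0978). TGF-beta targets fell in 11 of 20 cases and rose in 1, against 11 and 2 when adjusted over the list alone (median -0.27, camera adjusted p = 4.26e-06; adjusted p = 0.319 with an estimated correlation). These included TGFBI (-0.94) and PMEPA1 (-0.56), while BAMBI rose (0.67). BAMBI is a decoy receptor that restrains TGF-beta signalling. TGFBI and BAMBI did not pass without the block (limma adjusted p = 0.0890 and 0.147).

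**Figure D2:**
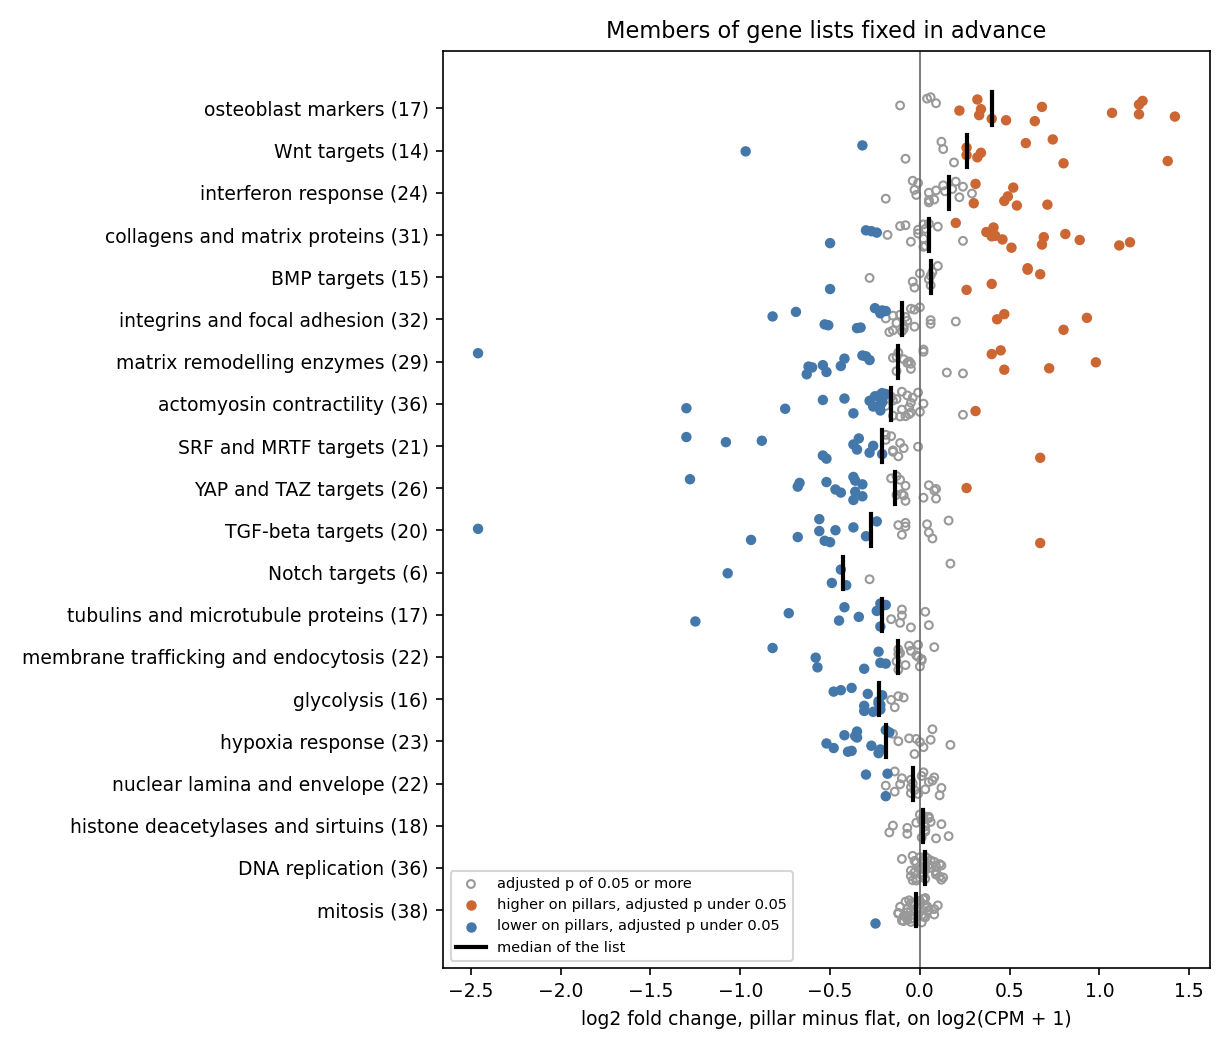
Each point is 1 gene of a fixed gene list, placed by its log2 fold change (pillar minus flat, n = 4 pairs). Filled points passed a limma adjusted p of 0.05, black bars are list medians, and the number of measured members stands beside each name. Medians run from -0.43 (Notch targets) to 0.40 (osteoblast markers), while histone deacetylases, DNA replication and mitosis lie near 0.

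Integrins and focal adhesion genes changed in both directions, 10 of 32 lower and 4 higher, against 13 and 5 when adjusted over the list alone (median -0.10, limma camera, Benjamini-Hochberg adjusted p = 0.00555; adjusted p = 0.326 with an estimated correlation). The laminin receptor subunit ITGA6 fell (-0.69), whereas the fibronectin receptor subunit ITGA4 (0.93) and the collagen receptor subunit ITGA11 (0.47) rose, as did ITGA10 (0.80) and ITGB5 (0.43). ITGA4 and ITGA11 did not pass without the block (limma adjusted p = 0.216 and 0.660). CAV1, the main protein of caveolae, fell from 379 ± 58.4 to 215 ± 36.1 CPM (-0.82, SE 0.05, adjusted p = 1.04e-07). In the membrane trafficking list, 7 of 22 members fell and none rose, with 7 also when adjusted over the list alone (median -0.12, camera adjusted p = 1.34e-04; adjusted p = 0.319 with an estimated correlation). Its 4 members of lowest p were the caveolar genes CAV1, CAV2 (-0.58) and CAVIN1 (-0.57) and the caveola-associated EHD2 (-0.31, adjusted p = 0.161 without the block). Tubulins and microtubule proteins fell in 10 of 17 cases with none higher, and in 11 when adjusted over the list alone (median -0.21, camera adjusted p = 7.06e-07; adjusted p = 0.319 with an estimated correlation). Examples were MAP1B (-1.25), TUBA4A (-0.73, from 326 ± 59.6 to 194 ± 18.6 CPM), TUBB6 (-0.45) and TUBB2A (-0.42). Among 8 intermediate filament genes, KRT80 (-0.89) and KRT18 (-0.33) fell, 3 genes when adjusted over the list alone (median -0.07, camera adjusted p = 0.0110; adjusted p = 0.319 with an estimated correlation). The intermediate filament list was not called without the block, with a random block or without the passage 11 pair, and KRT18 had an adjusted p of 0.525 without the block.

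Matrix genes moved apart. Of 31 collagens and matrix proteins, 13 rose and 4 fell, against 14 and 4 when adjusted over the list alone (median 0.05, mean 0.22, limma camera, Benjamini-Hochberg adjusted p = 9.63e-04; adjusted p = 0.319 with an estimated correlation). The collagen-binding proteoglycan LUM rose from 462 ± 120 to 1035 ± 230 CPM (log2 fold change 1.17, SE 0.07, limma adjusted p = 1.04e-07). THBS2 (0.89), LAMA4 (0.68, adjusted p = 0.0935 without the block) and the low-level COL3A1 (1.11, 0.808 ± 0.316 to 2.87 ± 0.430 CPM) rose too. COL6A3 (-0.50), THBS1 (-0.30), FBN1 (-0.27) and LAMC1 (-0.24) fell. COL1A1, the main collagen of bone, was at 6907 ± 946 CPM on flat and 6368 ± 470 CPM on pillars and did not pass (-0.11, 95% interval -0.26 to 0.04, adjusted p = 0.362). COL1A2, in the same list, rose (0.42, SE 0.06, limma adjusted p = 4.15e-04). Matrix remodelling enzymes and inhibitors fell in 11 of 29 cases and rose in 5, against 13 and 7 when adjusted over the list alone (median -0.12, camera adjusted p = 0.00406; adjusted p = 0.319 with an estimated correlation). This list was not called without the block. The metalloprotease ADAM12 fell (-0.63, adjusted p = 0.168 without the block), whereas the hyaluronan synthase HAS2 (0.98), the aggrecan-cleaving protease ADAMTS5 (0.72), MMP11 (0.47), LOXL3 (0.45) and MMP14 (0.40) rose.

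Genes of sugar metabolism and of the response to low oxygen fell by small amounts. In glycolysis, 12 of 16 enzymes fell and none rose, and 14 fell when adjusted over the list alone (median -0.23, limma camera, Benjamini-Hochberg adjusted p = 5.85e-09; adjusted p = 0.319 with an estimated correlation). LDHA, which makes lactate, fell from 1234 ± 127 to 947 ± 56.2 CPM (-0.38), and PFKP (-0.48), ENO2 (-0.44) and HK1 (-0.29) fell in 4 of 4 pairs. Of 23 hypoxia response genes, 13 fell and none rose, and 14 fell when adjusted over the list alone (median -0.19, camera adjusted p = 6.54e-06; adjusted p = 0.319 with an estimated correlation). Among them were the mitophagy receptor BNIP3 (-0.48), the glucose transporter SLC2A1 (-0.42), PDK1 (-0.35) and NDRG1 (-0.35, adjusted p = 0.125 without the block). Of 19 oxidative stress and metallothionein genes, 9 fell and 1 rose, against 11 and 1 when adjusted over the list alone (median -0.18, camera adjusted p = 6.04e-05; adjusted p = 0.319 with an estimated correlation). These included the ferritin light chain FTL (-0.45, 1565 ± 200 to 1137 ± 22.4 CPM), the cystine transporter SLC7A11 (-0.50, adjusted p = 0.0608 without the block) and the metallothionein MT1E (-0.30, adjusted p = 0.132 without the block). PIR was the member that rose (0.19).

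Signalling targets differed by pathway. Wnt targets rose in 8 of 14 cases and fell in 2, against 9 and 2 when adjusted over the list alone (median 0.26, limma camera, Benjamini-Hochberg adjusted p = 1.45e-04; adjusted p = 0.319 with an estimated correlation). The member with the lowest p was DKK1, a secreted inhibitor of Wnt signalling, which rose from 40.9 ± 13.8 to 108 ± 37.9 CPM (1.38), followed by the fall of cyclin CCND1 (-0.97) and the rise of APCDD1 (0.80), another inhibitor, and of the transcription factor TCF7 (0.59). CCND1 did not pass without the block (adjusted p = 0.0637), and DKK3 was the other member that fell (-0.32). Notch targets and components fell in 4 of 6 cases and in 5 when adjusted over the list alone, with none higher (median -0.43, camera adjusted p = 9.63e-04; adjusted p = 0.319 with an estimated correlation). The ligand JAG1 fell most (-1.07, SE 0.07, limma adjusted p = 1.29e-07), while NOTCH3 (-0.49), HES4 (-0.44) and HES1 (-0.41) did not pass without the block (adjusted p = 0.276, 0.189 and 0.0756). HES1 did not pass without the passage 8, 9 or 13 pair either (adjusted p = 0.131, 0.113 and 0.0555), nor HES4 without the passage 13 pair (adjusted p = 0.0880). BMP targets rose in 5 of 15 cases and fell in 1, the same counts as when adjusted over the list alone (median 0.06, camera adjusted p = 0.0408; adjusted p = 0.319 with an estimated correlation). The higher members were BAMBI, the secreted BMP antagonists GREM1 (0.60, adjusted p = 0.107 without the block) and NOG (0.60), DLX5 (0.40) and ATOH8 (0.26). SMAD7 fell (-0.50).

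Interferon response genes rose in 7 of 24 cases with none lower, and in 11 when adjusted over the list alone (median 0.16, limma camera, Benjamini-Hochberg adjusted p = 7.85e-05; adjusted p = 0.319 with an estimated correlation). IFITM1 rose from 10.9 ± 2.40 to 18.3 ± 2.17 CPM (0.71), and IFI44L (0.52) rose from under 2 CPM, at 1.97 ± 0.343. OAS3 (0.49) and DDX58 (0.54) did not pass without the block (limma adjusted p = 0.0610 and 0.159). Immediate early genes fell in 8 of 25 cases and rose in 3, against 10 and 3 when adjusted over the list alone (median -0.09, camera adjusted p = 0.0439; adjusted p = 0.514 with an estimated correlation). The phosphatase DUSP1 (-0.77, 181 ± 3.90 to 106 ± 12.6 CPM), JUN (-0.58) and EGR1 (-0.62, adjusted p = 0.192 without the block) fell. KLF4 (0.73, adjusted p = 0.290 without the block), FOS (0.41) and NR4A3 (0.37) rose. Neither the BMP nor the immediate early list was called without the block or without the passage 8 pair, nor BMP with a random block, without the passage 11 pair or after scaling to equal totals, or immediate early genes without the passage 13 pair, with a pseudocount of 0.1, with no filter, after removal of GC and length trends or in fry (adjusted p = 0.208).

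No histone deacetylase transcript passed the test. None of the 18 histone deacetylase and sirtuin genes passed over all genes or when adjusted over the list alone in limma, none passed in limma-voom, and 2 were lower at an unadjusted p under 0.05 (median 0.02, limma camera, Benjamini-Hochberg adjusted p = 0.866). HDAC2 (chromosome 6, 113933028 to 114011308) was at 334 ± 7.10 CPM on flat and 346 ± 9.93 CPM on pillars, a log2 fold change of 0.05 with a 95% interval of -0.05 to 0.16 (limma adjusted p = 0.563). HDAC1 (0.09, interval -0.01 to 0.20) and HDAC3 (0.03, interval -0.08 to 0.15) did not pass either, nor did the members of lowest p, SIRT7 (-0.15, adjusted p = 0.121), HDAC11 (-0.17, adjusted p = 0.178), HDAC4 (0.16, adjusted p = 0.207) and HDAC8 (0.12, adjusted p = 0.258). Among these 7 genes HDAC1, HDAC2 and HDAC8 were higher and SIRT7 lower in 4 of 4 pairs, while HDAC3, HDAC4 and HDAC11 differed in direction between pairs. Of 26 partners of HDAC1 and HDAC2 in their complexes, 3 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.38). The higher ones were RCOR2 (0.75), RBBP4 (0.16) and CHD3 (0.17), and the lower one SIN3B (-0.21). Of 24 genes of histone methylation and heterochromatin, 2 were higher and 1 lower, again the same adjusted over the list alone (camera adjusted p = 0.192), namely the DNA methyltransferase DNMT3A (0.27) and the demethylases KDM6B (0.24) and KDM4B (-0.29).

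In the nuclear lamina and envelope list, 3 of 22 members fell and none rose, 3 also when adjusted over the list alone, and the list as a whole was not called (median -0.04, limma camera, Benjamini-Hochberg adjusted p = 0.111), though fry called it lower (adjusted p = 0.0468). LBR (chromosome 1, 225401502 to 225428925), the lamin B receptor that ties heterochromatin to the inner nuclear membrane, fell from 200 ± 10.3 to 163 ± 7.55 CPM (log2 fold change -0.30, SE 0.05, limma adjusted p = 7.50e-04). The inner membrane protein TMEM43 (-0.18) and ANKLE2 (-0.19) fell by less, and neither passed without the block (adjusted p = 0.0971 and 0.0637), without the passage 9 pair (adjusted p = 0.131 and 0.0663), without the passage 13 pair (adjusted p = 0.15 and 0.145) or without a variance trend (adjusted p = 0.0640 and 0.0602). TMEM43 did not pass without the passage 11 pair either (adjusted p = 0.0531). The A-type lamin gene LMNA (1115 ± 107 against 1038 ± 40.6 CPM, -0.10, adjusted p = 0.344), LMNB1 (0.12, adjusted p = 0.187), SUN1 (-0.14, adjusted p = 0.0729), SUN2 (0.01, adjusted p = 0.967) and EMD (-0.03, adjusted p = 0.761) did not pass. Without the passage 8 pair SUN1 passed (adjusted p = 0.0436), SUN2 was at -0.01 and EMD at 0.01, and SUN2 was at -0.01 and -0.03 without passages 9 and 11. Of 26 nucleoporins 1 was higher (NUP210, 0.23; camera adjusted p = 0.698), and of 10 mechanosensitive channels 1 was higher (TMEM63A, 0.33) and 1 lower (PIEZO1, -0.32; camera adjusted p = 0.853), with the same counts adjusted over the list alone.

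**Figure D3:**
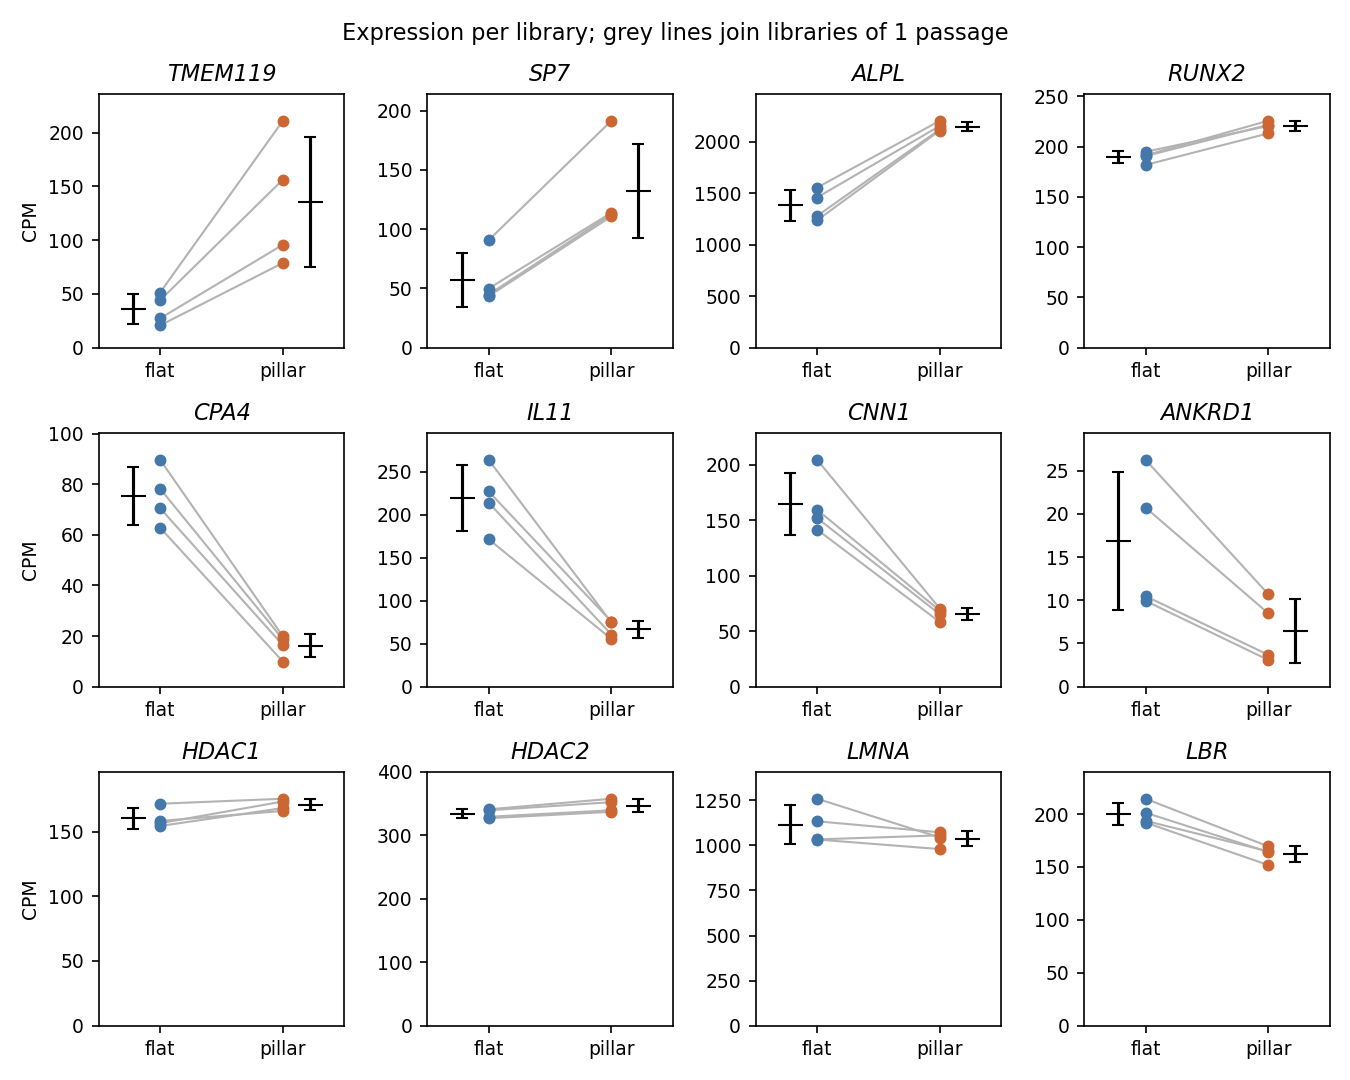
Expression of 12 genes in CPM per library on flat and pillar surfaces, with grey lines joining libraries of 1 passage and black bars beside the points giving the mean and SD (n = 4). TMEM119, SP7 and ALPL are higher on pillars and CPA4, IL11, CNN1, ANKRD1 and LBR lower in each of the 4 passages. HDAC1 and HDAC2 are also higher in each of the 4 passages, by small amounts, but did not pass, and LMNA did not pass either.

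Neither of the cell cycle lists was called. None of 36 DNA replication genes passed in limma over all genes, when adjusted over the list alone or in limma-voom, with 3 higher at an unadjusted p under 0.05 (median 0.03, limma camera, Benjamini-Hochberg adjusted p = 0.319), though the list was called higher without the passage 13 pair (median 0.05, adjusted p = 0.0452). Of 38 mitosis genes 1 was lower (ANLN, -0.25), also when adjusted over the list alone (median -0.02, camera adjusted p = 0.235), and the proliferation marker MKI67 was at 471 ± 106 CPM on flat and 495 ± 21.7 CPM on pillars (0.10, limma adjusted p = 0.566, and -0.07 without the passage 8 pair). None of 24 homologous recombination and Fanconi genes passed in limma or limma-voom, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.503).

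Other lists not called were, with members higher and lower over all genes in limma, cholesterol synthesis (1 and 0 of 23, camera with Benjamini-Hochberg adjusted p = 0.853), fatty acid synthesis (1 and 1 of 17, adjusted p = 0.866) and the heat shock response (0 and 1 of 18, adjusted p = 0.38). The members passing were HMGCS1 (0.22), FADS2 (0.23), ACLY (-0.23) and HSPB1 (-0.34). Adjusted over the list alone, these counts were the same. The integrated stress and unfolded protein response had 3 higher and 9 lower of 28, against 6 and 10 when adjusted over the list alone (adjusted p = 0.222), and was called lower without the passage 11 pair (median -0.15, adjusted p = 0.00665). NF-kB targets and cytokines had 2 higher and 4 lower of 12, the same adjusted over the list alone (adjusted p = 0.101): CSF1 (0.46) and NFKBIA (0.27) against IL11, LIF (-1.29), IER3 (-0.97) and TNFAIP2 (-0.32). This list was called lower with a pseudocount of 4 (adjusted p = 0.0447), with no filter (0.0402), with a mean of at least 5 CPM (0.0157), in limma-voom (0.0458), in camera with a variance trend (0.0378) and in fry (0.00258). Lysosome and autophagy had 2 higher (HEXA, 0.19, among them) and 2 lower (CTSL and MAP1LC3B) of 27, against 4 and 2 when adjusted over the list alone (adjusted p = 0.957). None of 36 nuclear oxidative phosphorylation genes passed in limma or limma-voom, with 2 lower at an unadjusted p under 0.05 (adjusted p = 0.621).

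Markers of other cell types moved in both directions or were scarce. Of 11 fibroblast and smooth muscle markers, 3 were higher and 5 lower in limma, against 4 and 5 when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.334), and fry called the list lower (adjusted p = 0.0234). LUM, DCN (0.69) and PDGFRA (0.55) were higher, and CNN1, CSPG4 (-0.56), PDGFRB (-0.54), ACTA2 (-0.52) and MCAM (-0.36) lower. Adipocyte (3 measured, PPARG lower), epithelial (1 measured, EPCAM higher), endothelial (2 measured, none passing in limma or limma-voom or at an unadjusted p under 0.05) and immune cell markers (2 measured, CD68 lower) had too few members for a list test. As signs of RNA quality and selection, 13 transcripts of the mitochondrial genome had a median log2 fold change of 0.10, with none passing in limma or limma-voom and 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0131; adjusted p = 0.514 with an estimated correlation). ND6 passed without the passage 8 pair (0.24, adjusted p = 0.0253) and ND1 after quantile normalization (0.16, adjusted p = 0.0444). The 15 replication-dependent histone genes had a median of -0.15, with none passing in limma or limma-voom and 1 higher and 7 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0278; adjusted p = 0.542 with an estimated correlation). Without the passage 11 pair H2AC18 (-1.05), H2BC8 (-0.34), H4C14 (-0.27) and H2BC21 (-0.25) passed, H2BC8 lay close to the threshold and passed in most other limma fits (adjusted p = 0.0314 with a random block), and H4C14 passed after removal of GC and length trends (adjusted p = 0.0487). Of 56 ribosomal protein genes none passed in limma or limma-voom, with 1 lower at an unadjusted p under 0.05 (median -0.04, camera adjusted p = 0.0686), but the list was called lower without the passage 11 pair (median -0.08, adjusted p = 1.71e-04). The histone list was not called without the block, with a robust variance or without the passage 8 pair, and neither it nor the mitochondrial list was called without the passage 13 pair or in fry (adjusted p = 0.199 and 0.0806).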

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

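The tests of depth and of GC content and transcript length were planned before their results were seen, while the comparison of passage 11 with the pillar effect, the share of the most abundant genes and the count of pairs at that passage were chosen after. The depth test replaced a weaker one that had been run. Among 248 groups of 4 libraries, 1 per named gene and surface plus those of the library measures, 22 had a highest or lowest library whose gap to the nearest other, as a share of the range, exceeded Dixon's critical value, where chance gives about 1 in 20, or 12.4. Of these 22, 19 were at passage 11. The groups are not independent, since genes of 1 list vary together and each gene was counted on both surfaces. SP7, BAMBI and DKK1 were flagged on both, so 12.4 is only a guide. On flat, the passage 11 library was highest for EPYC (21.1 CPM, gap 0.850 of the range), IFITM5 (0.921), ITGA4 (0.886), SP7 (90.7 CPM, 0.862), BAMBI (0.912), DKK1 (0.922) and SLC7A11 (0.903), and lowest for CAV1 (0.858) and JUN (0.876). On pillars it was highest for INSC (0.890), PHOSPHO1 (0.882), PANX3 (0.923), SP7 (192 CPM, 0.962), BAMBI (0.877), DKK1 (0.911) and TCF7 (0.922), and lowest for LDHA (0.901), NOTCH3 (0.845) and EHD2 (0.941). The remaining 3 were MKI67, lowest in the flat library of passage 8 (313 CPM against a median of 526, gap 0.858), SLC2A1, highest in the flat library of passage 13 (0.846), and H4C14, highest in the pillar library of passage 9 (0.843).

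The passage 11 libraries departed from the others partly along the genes that differed between surfaces: across genes, which are not independent replicates, the deviation of passage 11 correlated with the pillar effect at r = 0.35, against -0.17, -0.27 and -0.07 for passages 8, 9 and 13, which are bound to balance it. Of 312 genes higher at passage 11 163 were also higher on pillars (22 for independent lists) and 20 lower, and of 435 genes lower at passage 11 179 were also lower on pillars (32 for independent lists) and 57 higher. Passage 11 was 1 pair, and both sets of genes came from the same libraries. The counts for independent lists are therefore only a guide and no test of the overlap. After thinning all libraries to the shallowest, r was 0.34, and after removal of GC and length trends it was 0.35. The share of the 10 most abundant genes differed by at most 0.97 percentage points, so none of these accounts for it as the whole cause. The state of the culture at that passage may do so, but with 1 flat and pillar pair at passage 11 it cannot be told apart from any other property of that pair.

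The number of genes was set against other splits of the 8 libraries. Without the block, 1 of 35 splits, the real one, gave as many as 591 genes (highest other 11). It was also the only one with as many as 195 genes changed at least 1.5-fold (highest other 9). These splits leave the pairing by passage aside, and most of them part fewer pairs than the real one. They therefore cannot exclude chance in this paired design. With the block, the 8 splits that part every passage pair are too few for a share under 0.05. The real values were 1826 and 317 genes, and the highest other value was 0 for both, each reached by 1 of 8 splits. For the number of lists called chance cannot be excluded: 11 of 35 splits without the block gave at least the real 16 (highest other 26), and 2 of 8 with the block gave at least the real 22 (highest other 23), again too few splits for a share under 0.05. Taken list by list, the mean log2 fold change of 12 of the 22 called lists was larger in the real split than in any other of the 35, but so was that of lists not called, such as the HDAC1 and HDAC2 partners and NF-kB targets, and none passed when these p-values were adjusted by Benjamini-Hochberg (lowest 0.078). Of the 8 splits that part every passage pair, the real one gave the largest mean for 20 of the 22, but the smallest p possible there is 0.125.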

How the results depend on the processing

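The settings chosen after the data were seen were limma-voom, the removal of GC and length trends, thinning, and camera with a variance trend. Since camera takes no random block or robust variance, lists were tested in those fits on their moderated t by cameraPR, also chosen after. As camera had no variance trend, the fit without one could not alter a list. Over the 18 other fits, the number of genes passed stayed within 1.5 times of 1826, except for 591 with no replicate block, where pairing by passage is given up, and 1022 without the passage 13 pair (range 1022 to 1824 with 1 pair left out). The count of genes changed at least 1.5-fold (317) became 195 with no replicate block and 178 with a pseudocount of 4, which shrinks folds of low genes, 441 with one of 0.1 and 459 in limma-voom, and ran from 305 to 342 with 1 pair left out. The number of lists (22) ran from 16 to 23 over 18 list tests, 18 to 22 with 1 pair left out, and was 0 with an estimated correlation in camera, where 4 lists had an unadjusted p under 0.05. Of the 22 lists, 15 stayed called in the same direction in all 18 tests, and of 96 named genes past the threshold 64 did so in all 18 fits, while 30 were lost without the block. Scaling to equal totals gave 1006 higher and 777 lower genes, against 895 and 931, and limma-voom gave 1808 genes, 1780 of them shared. The edgeR count model planned for recovered reads was not run, because only 72.9% to 74.1% of values were whole reads. Some lists not called were called in 1 or more of these fits: cytosolic ribosomal proteins and the integrated stress response without passage 11, DNA replication without passage 13, and NF-kB targets in 5. No called result changed direction. Some results that had not passed changed direction, and the cause was not tested. With 1 pair left out these were SUN2 (-0.03 to 0.06), EMD (-0.07 to 0.01) and MKI67 (-0.07 to 0.17, at -0.07 without passage 8). The lists whose direction in camera did so, with the range of their medians, were histone deacetylases (-0.01 to 0.04), nucleoporins (-0.02 to 0.03), mechanosensitive channels (0.02 to 0.07) and homologous recombination (0 to 0.09). The others were cholesterol synthesis (-0.08 to 0.02), fatty acid synthesis (0.01 to 0.04), lysosome (0 to 0.03), oxidative phosphorylation (-0.05 to 0.04) and ribosomal proteins (-0.08 to 0.01). The direction is that of camera and not always of the median, which stayed positive for mechanosensitive channels and fatty acid synthesis. Fatty acid synthesis also turned with no replicate block and with a random block (both 0.04), cholesterol synthesis with quantiles (-0.02), and lysosome with quantiles (0.05), a random block, a robust variance, a camera trend and limma-voom (all 0.04) and GC and length removed (0.03). Differences in depth between libraries mattered little, since thinning to the shallowest gave 1825 genes, 1741 of them shared.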

Other observations

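The gene groups of the next paragraph were chosen after the data were seen, as were the tests of dividing cells and of the chorionic gonadotropin copies, whereas the tests of GC and length, of depth and of leaving out passage 11 were planned before their results were seen. Because some members had prompted the choice of a group, each group was tested again on the members whose values had not been seen. That left out named genes, members of earlier lists and others such as PTCH1 and MEF2C, a choice not fixed in advance. The remaining members come from the same libraries and may vary together with those that prompted the choice, so the second test is not independent.

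Components and targets of the Hedgehog pathway were higher on pillars in 6 of 10 measured cases, with none lower. The receptor and target gene PTCH1, which had prompted the choice, went from 46.4 to 95.5 CPM, HHIP, another target, from 16.7 to 27.5 CPM (0.68), GLI2 from 29.8 to 46.2 CPM (0.66), and GLI1, the usual readout of the pathway, by 0.28 (limma adjusted p = 0.0212). On the 9 members not seen before, of which 5 were higher, limma camera gave an adjusted p of 2.97e-04, and adjusted p = 0.126 with an estimated correlation. Of 12 late osteoblast and osteocyte genes 9 were higher, among them MEF2C (127 to 216 CPM), SMPD3 (3.52 to 10.8 CPM) and the osteocyte gene SOST (0.924 to 3.87 CPM), and for the 5 members not seen before, of which 2 were higher (COL24A1 and SPNS2), the adjusted p was 0.0187 (adjusted p = 0.126 with an estimated correlation). Of 14 ERK pathway output genes 6 were lower and 1 higher, but the 6 members not seen before, of which 1 was higher and none lower, did not pass as a group (camera adjusted p = 0.70). Placental hormone genes were lower in 5 of 5 measured cases, including CGB7 (-1.04) and PSG1 (-1.08), and with 1 member not seen before no test was possible. Both Hedgehog and late osteoblast genes are therefore hypotheses to follow up, each found and tested on the same libraries.

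Higher osteoblast markers beside lower actomyosin, YAP and TAZ, SRF and MRTF, and TGF-beta lists formed the main pattern. Of these 5 lists, 5 were still called in the same direction after GC and length trends were removed, with 0.95 to 1.02 of their medians, 5 after thinning to the shallowest library, and 5 without the passage 11 pair, so none of the 3 explains the pattern as its whole cause. As to fewer dividing cells on pillars, 1 of 74 members of the DNA replication and mitosis lists was lower, and their medians were 0.03 and -0.02. These values argue against a large fall in dividing cells, but the limits of that test were set after they had been seen. The replication-dependent histone list was called lower (median -0.15), so a smaller difference stays open. A response of the cells to the pillared surface may underlie the pattern, and differences in cell density or spreading between the surfaces stay open, since no such measure was tested. Whether RNA quality or selection contributed was not tested either. The mitochondrial list was called higher and the replication-dependent histone list lower (limma camera adjusted p = 0.0131 and 0.0278, and 0.514 and 0.542 with an estimated correlation). None of the 5 lists passed in camera with an estimated correlation, whereas all 5 passed in fry (adjusted p = 0.00106 to 0.0215).

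CGB3, CGB5 and CGB8 were among the largest falls, and none of their values were whole reads (0%), so reads had been divided between copies. Reads moving from 1 copy to another do not explain the falls, because 4 of 4 measured copies were lower and the summed CPM of the family had a log2 fold change of -1.96 (SD over pairs 0.09), from 93.9 ± 17.8 to 23.4 ± 5.29 CPM. Which copy is expressed stays open, and no biological explanation for the fall was tested.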
